A study of Mus musculus with 12 samples.

How the data were processed

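RNA was extracted from homogenized lung of C57BL/6J mice with an age label of 8 weeks, and libraries were built and sequenced on a BGISEQ 500, per the labels' protocols. Samples were sequenced where the RNA integrity number was above 7 and the 28S to 18S ratio above 1, per the labels' protocols. Reads were processed with HISAT and RSEM 1.2.12 against mm10, per the labels. The expected counts per gene were made by the authors with RSEM and deposited without scaling to depth, per the file headers. The FPKM values (fragments scaled to transcript length and library size) were computed by the authors and deposited beside the counts, per the file headers. The HISAT version, the strandedness of the libraries and the annotation release are not given in the sources used here.

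Each library had 1 deposited table, and a combined FPKM table had 12 columns of values, of which 0 could not be assigned and whose largest difference from the single tables was 0. The tables listed 20774 genes together, with a lowest listed FPKM of 0.01, and a gene missing from a table was taken as 0 there. Of the expected counts 73.3% were whole numbers, and counts were rounded. Gene symbols that a spreadsheet had turned into dates numbered 27 and were replaced from the gene IDs. Groups, replicate numbers and times came from the labels. Coordinates of 20718 genes came from the NCBI gene table of GRCm38, matched on gene ID. Gene length differed between libraries for 24.69% of genes, so FPKM served only in alternatives. Between libraries of a group, chi-square per degree of freedom was 7.12 to 15.4, except the pairs of PQ 4w replicate 3, at 30.8 and 32.9, so no library repeated another.

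The main test was edgeR's quasi-likelihood F-test (glmQLFit and glmQLFTest) on the rounded expected counts of all 12 libraries with 4 group means, TMM scaling and filterByExpr (minimum count 10, minimum total count 15), which kept 15921 genes. TMM factors were 0.974 to 1.06. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were PQ against control at 1w and at 4w, the difference of these effects (interaction term), PQ 4w against PQ 1w and control 4w against control 1w. Standard errors of log2 effects are approximate: the absolute effect was divided by the square root of its F statistic. CPM were computed from the deposited counts with TMM factors, and principal components from log2 CPM with a prior count of 2. Calls shared by the times were set beside the number that independent lists of the same sizes would share. A fold against 0 counts was computed against a floor of 3 counts over the group, and one against 1 to 3 counts was given as a ratio with its 95% interval. These intervals and the floor cover counting error only. R 4.3.3 ran edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 ran pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

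The groups, tests, gene lists, named gene rule and alternatives were set before the data were examined. The 45 lists were fibrillar and other interstitial collagens, basement membrane, collagen processing and crosslinking, matrix glycoproteins and proteoglycans, matrix proteases and inhibitors, TGF-beta family signalling, smooth muscle and myofibroblast, alveolar fibroblast, adventitial fibroblast, pericyte, mesothelium, alveolar type 2 epithelium, alveolar type 1 epithelium, transitional alveolar epithelium, club and mucous airway epithelium, ciliated airway epithelium, basal airway epithelium, all endothelium, capillary endothelium, alveolar macrophage, monocyte-derived and tissue macrophage, monocyte, neutrophil, dendritic cell, T cell, NK cell, B cell, plasma cell, lymphoid follicle, inflammatory chemokines and cytokines, interferon-induced, complement, antioxidant and NRF2 targets, p53 targets, proliferation, xenobiotic metabolism, lipid synthesis and cholesterol, glycolysis and hypoxia, nuclear-encoded mitochondrial complex I, endoplasmic reticulum stress, circadian clock, immediate early, erythroid, cardiac muscle, adipocyte. Of 822 listed symbols 814 matched the tables, and of the 775 genes in any list 39 were in more than 1. The whole lung expresses genes of every list, so a list is a set of transcripts and not a count of cells. Lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 45 lists of a comparison, and again with an estimated correlation and with fry. Members were also counted with Benjamini-Hochberg adjustment over the list alone. The level of a list in a library was the mean over its genes of log2 (CPM + 0.5) minus the mean of the 6 controls.

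Genes were named by a rule with 3 parts for PQ against control at each time. The first was the 5 highest and 5 lowest log2 effects among genes with adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the 3 treated and 3 control values, without predicted, immunoglobulin segment, T cell receptor segment and histone genes. The next was the 2 members with the smallest p, called in the direction of the list, of each of the 8 lists with the smallest camera p. The last was Col1a1, Col3a1, Fn1, Acta2, Timp1, Tgfb1, Cdkn1a, Sftpc, Ager and Mki67. The other 3 comparisons used the first part, without the overlap condition for the difference of effects. Genes outside the rule are marked as chosen after their values were seen, and 1 member of a list, kept in its counts and tests, is not reported here by itself.

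The procedure first ran on counts simulated from the means and sizes of these libraries. In them 200 genes changed, 50 each at 1.5-, 2-, 4- and 8-fold. At 1w (15775 genes) 64%, 90%, 100% and 100% were recovered, with 6 of 183 calls (3.28%) false. At 4w (15755 genes) 50%, 84%, 98% and 98% were recovered, with 4 of 169 calls (2.37%) false. These rates may not hold for the wider PQ 4w spread. Alternatives were median-of-ratios size factors, total counts, no filter, a mean CPM of at least 1, the DESeq2 Wald test, limma with trend on log2 (FPKM + 1) and log2 (FPKM + 0.1) with a mean FPKM of at least 1, limma with no filter, only the 6 libraries compared, a 2-fold minimum and each library left out in turn. Library labels were also regrouped in all 10 splits of each pair of groups, and in 100 drawn of 200 possible splits for the difference of effects (seed 7). No reads were processed, and isoforms were not examined.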

Results

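Lung transcript levels were measured in wild-type C57BL/6J mice given a single intratracheal dose of paraquat (PQ), a herbicide, or of saline. The deposited tables held expected counts per gene for 12 libraries in 4 groups of 3: saline control at 1w, PQ at 1w, saline control at 4w and PQ at 4w. The time labels 1w and 4w were read as weeks. Library totals were 17220978 to 18559809 expected counts, and 15921 of 20774 genes were tested. Replicates were numbered and not stated to be separate animals, so p-values measure only the spread between these samples. Effects and adjusted p-values came from an edgeR quasi-likelihood fit of all 12 libraries with Benjamini-Hochberg adjustment, n = 3 per group throughout, and ± marks a standard error of a log2 effect or an SD of CPM, counts scaled to library size. Genes rose or fell where adjusted p was under 0.05, and 45 gene lists fixed beforehand were tested with camera. Coordinates refer to GRCm38 (mm10).

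The PQ 1w libraries lay apart from all others in principal components of log2 CPM. Component 1 held 51.1% of the variance, with PQ 1w libraries at 68.9 to 73.8 and the other 9 libraries at -40.6 to -6.19. On component 2 (19.9%), PQ 4w replicates 1 and 2 were at -42.0 and -40.3 and replicate 3 at 4.92. Replicate 3 of PQ 4w also differed in transcripts of airway cells: Scgb1a1, a secreted protein of club cells, made up 2.08% of its counts against 3.29% and 4.19% in replicates 1 and 2. That share was 1.94 to 2.75% in control 1w, 0.349 to 0.479% in PQ 1w and 4.00 to 4.73% in control 4w.

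**Figure D1:**
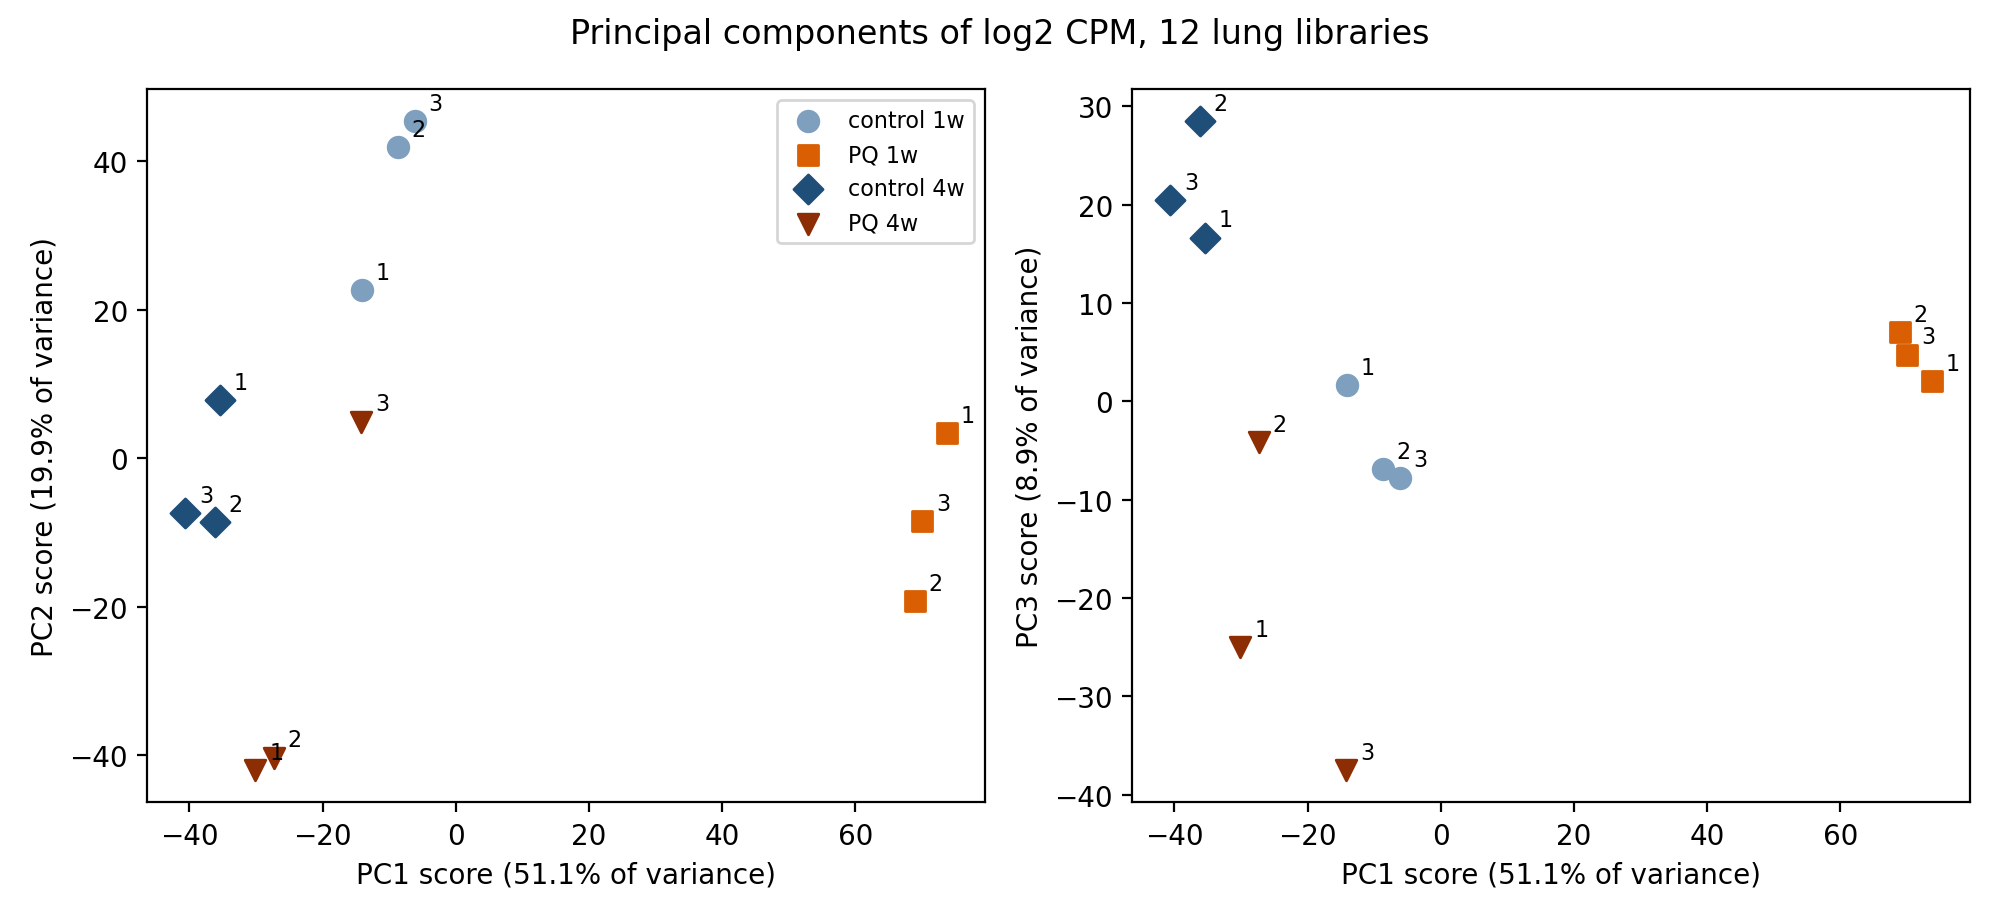
Principal components of log2 CPM for the 12 libraries, component 1 (51.1% of variance) against components 2 (19.9%) and 3 (8.91%), coloured by group, 1 point per library. PQ 1w lay at 68.9 to 73.8 on component 1.

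At 1w, genes of the collagen matrix rose. All 15 interstitial collagen genes rose, with a median log2 of 1.90. Col1a1, the alpha 1 chain of type I collagen (chromosome 11, 94936224 to 94953042), rose 6.34-fold (log2 2.66 ± 0.09, adjusted p = 6.67e-09), from 636 ± 24.8 to 4031 ± 358 CPM. Col1a2, its partner chain, rose 4.57-fold (log2 2.19 ± 0.07, adjusted p = 5.34e-09), and Col3a1, type III collagen (chromosome 1, 45311538 to 45349706), rose 3.74-fold (log2 1.90 ± 0.10, adjusted p = 8.44e-08). Fn1, which encodes fibronectin (chromosome 1, 71585473 to 71653280), rose 7.19-fold (log2 2.85 ± 0.19, adjusted p = 3.94e-07). Tnc, which encodes the matrix glycoprotein tenascin-C (chromosome 4, 63959785 to 64047015), rose 12.95-fold (log2 3.69 ± 0.19, adjusted p = 5.85e-08), from 37.7 ± 1.60 to 488 ± 109.5 CPM. Fbn1, the microfibril protein fibrillin, rose 3.52-fold (adjusted p = 1.93e-07). Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874737), rose 10.6-fold (log2 3.41 ± 0.18, adjusted p = 8.81e-08). The membrane metalloproteinase Mmp14 rose 4.72-fold (adjusted p = 1.07e-08), and Ctsk, the collagen-degrading cathepsin K, rose 9.62-fold (adjusted p = 2.69e-08). Proteins of collagen assembly, the collagen chaperone Fkbp10 and the crosslinking enzyme Loxl3, rose 3.85-fold (adjusted p = 1.32e-08) and 2.86-fold (adjusted p = 9.54e-08).

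The 5 matrix lists passed higher at 1w. The collagen list passed at adjusted p = 2.45e-35, 0.00178 with an estimated correlation, with 15 genes rising adjusted over the list alone. Of 25 matrix glycoproteins and proteoglycans, 20 rose, 1 fell and 4 did not pass (20 and 1 adjusted over the list alone). Median log2 was 1.204, with adjusted p = 2.62e-15, 0.0139 with an estimated correlation. Of 23 matrix proteases and inhibitors, 15 rose, 1 fell and 7 did not pass (15 and 1 adjusted over the list alone). Median log2 was 0.90, with adjusted p = 7.27e-12, 0.00241 with an estimated correlation. Of 17 genes for collagen processing and crosslinking, 11 rose, 1 fell and 5 did not pass (13 and 1 adjusted over the list alone). Median log2 was 0.93, with adjusted p = 7.89e-11, 0.0171 with an estimated correlation. In the basement membrane list of 21, 14 rose, 2 fell and 5 did not pass (14 and 2 adjusted over the list alone). Median log2 was 0.50, with adjusted p = 0.00047, 0.445 with an estimated correlation. Tgfb1, the cytokine TGF-beta 1, rose 1.28-fold (adjusted p = 0.00671), and of 24 genes of TGF-beta family signalling, 14 rose, 6 fell and 4 did not pass (14 and 6 adjusted over the list alone). Median log2 was 0.30, with adjusted p = 0.0283, 0.404 with an estimated correlation. Acta2, the smooth muscle actin of myofibroblasts, rose 2.71-fold (adjusted p = 3.5e-05), while the smooth muscle and myofibroblast list did not pass: 6 rose, 2 fell and 5 did not pass, 6 and 2 adjusted over the list alone, adjusted p = 0.288. Adventitial fibroblast genes numbered 12, of which 6 rose, 0 fell and 6 did not pass (6 and 0 adjusted over the list alone). Median log2 was 0.40, with adjusted p = 0.000919, 0.226 with an estimated correlation. Of 14 alveolar fibroblast genes, 2 rose, 10 fell and 2 did not pass (2 and 10 adjusted over the list alone). Median log2 was -0.51, with adjusted p = 1.89e-06, 0.0469 with an estimated correlation. Ces1d, a carboxylesterase of lipofibroblasts, fell 3.01-fold (log2 -1.59 ± 0.07, adjusted p = 2.22e-08).

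Cell division genes and macrophage genes also rose at 1w. All 29 proliferation genes rose, the same 29 adjusted over the list alone, with a median log2 of 2.17 (adjusted p = 1.43e-48, 0.0139 with an estimated correlation). Foxm1, a transcription factor of dividing cells, rose 5.46-fold (log2 2.45 ± 0.10, adjusted p = 1.32e-08), Birc5, the mitotic protein survivin, rose 5.12-fold (log2 2.35 ± 0.12, adjusted p = 5.01e-08), and Mki67, the marker Ki-67, rose 4.63-fold (log2 2.21 ± 0.20, adjusted p = 3.52e-06). Gpnmb, a glycoprotein of lipid-laden macrophages (chromosome 6, 49036518 to 49058182), rose 6.50-fold (log2 2.70 ± 0.13, adjusted p = 2.99e-08), from 15.6 ± 0.505 to 101 ± 4.17 CPM. Cd68, a lysosomal macrophage marker, rose 3.66-fold (log2 1.87 ± 0.08, adjusted p = 2.1e-08). Of 20 monocyte-derived and tissue macrophage genes, 15 rose, 0 fell and 5 did not pass (16 and 0 adjusted over the list alone). Median log2 was 1.68, with adjusted p = 1.25e-19, 0.00178 with an estimated correlation. Among 18 alveolar macrophage genes, 10 rose, 4 fell and 4 did not pass (10 and 4 adjusted over the list alone). Median log2 was 0.59, with adjusted p = 0.0107, 0.408 with an estimated correlation. Ccl2, a chemokine that attracts monocytes and a gene named after its value was seen, rose 17.1-fold (adjusted p = 1.01e-05). Of 26 inflammatory chemokines and cytokines, 15 rose, 4 fell and 7 did not pass (15 and 4 adjusted over the list alone). Median log2 was 0.96, with adjusted p = 0.0304, 0.408 with an estimated correlation. The 21 complement genes divided too: 9 rose, 4 fell and 8 did not pass (9 and 4 adjusted over the list alone). Median log2 was 0.37, with adjusted p = 0.00382, 0.404 with an estimated correlation.

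Lymphocyte transcripts fell at 1w. All 14 NK cell genes fell, 14 adjusted over the list alone, with a median log2 of -2.60 (adjusted p = 6.63e-16, 0.0553 with an estimated correlation). Gzma, the cytotoxic protease granzyme A (chromosome 13, 113093824 to 113100981), fell 8.57-fold (log2 -3.10 ± 0.24, adjusted p = 1.04e-06), from 45.7 ± 6.70 to 5.33 ± 1.54 CPM. Klrb1c, the receptor NK1.1, fell 5.81-fold (log2 -2.54 ± 0.20, adjusted p = 1.06e-06). Of 16 B cell genes, 0 rose, 14 fell and 2 did not pass (0 and 14 adjusted over the list alone). Median log2 was -2.07, with adjusted p = 4.62e-07, 0.404 with an estimated correlation. Among 19 T cell genes, 0 rose, 17 fell and 2 did not pass (0 and 18 adjusted over the list alone). Median log2 was -1.19, with adjusted p = 1.96e-06, 0.404 with an estimated correlation. Cd3e, a receptor gene of T cells picked after its values were seen, was at 0.309 times the control (adjusted p = 0.000583). Of 12 lymphoid follicle genes, 1 rose, 6 fell and 5 did not pass (2 and 7 adjusted over the list alone). Median log2 was -0.70, with adjusted p = 0.0137, 0.408 with an estimated correlation. In the dendritic cell list of 15, 3 rose, 9 fell and 3 did not pass (3 and 11 adjusted over the list alone). Median log2 was -0.69, with adjusted p = 0.044, 0.408 with an estimated correlation. Of 25 interferon-induced genes, 0 rose, 10 fell and 15 did not pass (0 and 8 adjusted over the list alone). Median log2 was -0.55, with adjusted p = 0.0144, 0.746 with an estimated correlation. Among 13 erythroid genes, 0 rose, 7 fell and 6 did not pass (0 and 8 adjusted over the list alone). Median log2 was -1.44, with adjusted p = 0.0419, 0.614 with an estimated correlation.

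Transcripts of alveolar type 2 epithelium and endothelium mostly fell at 1w. Sftpc, surfactant protein C of alveolar type 2 cells, was at 0.536 times the control (adjusted p = 5.4e-05), and Ager, a receptor of alveolar type 1 cells, was at 0.770 times the control and did not pass (adjusted p = 0.0926). Of 17 alveolar type 2 epithelium genes, 0 rose, 12 fell and 5 did not pass (0 and 12 adjusted over the list alone). Median log2 was -0.48, with adjusted p = 0.00012, 0.404 with an estimated correlation. Of 16 alveolar type 1 epithelium genes, 2 rose, 6 fell and 8 did not pass, 2 and 6 adjusted over the list alone, adjusted p = 0.181. The transitional alveolar epithelium list of 16 moved the other way: 14 rose, 1 fell and 1 did not pass (14 and 1 adjusted over the list alone). Median log2 was 0.96, with adjusted p = 2.38e-05, 0.15 with an estimated correlation. Of 18 genes of all endothelium, 1 rose, 14 fell and 3 did not pass (1 and 14 adjusted over the list alone). Median log2 was -0.58, with adjusted p = 0.000267, 0.408 with an estimated correlation. Of 18 capillary endothelium genes, 1 rose, 11 fell and 6 did not pass (1 and 12 adjusted over the list alone). Median log2 was -0.78, with adjusted p = 0.000179, 0.404 with an estimated correlation. Aox3, an aldehyde oxidase, fell 5.60-fold (log2 -2.49 ± 0.12, adjusted p = 3.05e-08), and of 23 xenobiotic metabolism genes, 1 rose, 16 fell and 6 did not pass (1 and 16 adjusted over the list alone). Median log2 was -0.81, with adjusted p = 2.82e-11, 0.125 with an estimated correlation. These lists moved in the libraries in which the Scgb1a1 share was lowest. That share is of 1 gene, a member of the club and mucous list, so it is not an independent measure of airway tissue. Relative to the 6 controls, the club and mucous list was at log2 -0.609 in PQ 1w and -0.743 in control 1w. The ciliated list was at -1.047 and -0.5. Of 15 club and mucous airway epithelium genes, 1 rose, 5 fell and 9 did not pass (1 and 5 adjusted over the list alone). Median log2 was 0.08, with adjusted p = 0.00608, 0.594 with an estimated correlation. Of 20 ciliated airway epithelium genes, 0 rose, 5 fell and 15 did not pass (0 and 2 adjusted over the list alone). Median log2 was -0.60, with adjusted p = 0.0201, 0.746 with an estimated correlation.

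Further lists of cell state divided at 1w. Cdkn1a, the cell cycle inhibitor p21, was at 0.643 times the control (adjusted p = 0.0069), although the p53 targets list of 22 passed higher: 10 rose, 5 fell and 7 did not pass (11 and 5 adjusted over the list alone). Median log2 was 0.19, with adjusted p = 0.021, 0.404 with an estimated correlation. Of 20 genes of glycolysis and hypoxia, 10 rose, 1 fell and 9 did not pass (12 and 1 adjusted over the list alone). Median log2 was 0.34, with adjusted p = 5.5e-05, 0.0571 with an estimated correlation. Of 23 genes of mitochondrial complex I, 14 rose, 0 fell and 9 did not pass (15 and 0 adjusted over the list alone). Median log2 was 0.28, with adjusted p = 0.021, 0.721 with an estimated correlation. Of 20 genes of endoplasmic reticulum stress, 0 rose, 10 fell and 10 did not pass (0 and 10 adjusted over the list alone). Median log2 was -0.28, with adjusted p = 0.00608, 0.507 with an estimated correlation. The antioxidant and NRF2 targets list of 29 did not pass, though 11 genes rose and 7 fell, 11 and 8 adjusted over the list alone (adjusted p = 0.852). Hmox1, the heme-degrading enzyme of oxidative stress, rose 6.61-fold (adjusted p = 4.46e-07), and Cat, the peroxide-degrading enzyme catalase, was at 0.458 times the control (adjusted p = 8.44e-08). Both were chosen after their values were seen. Of 17 circadian clock genes, 6 rose, 6 fell and 5 did not pass, 6 and 6 adjusted over the list alone, adjusted p = 0.677.

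Single genes with the largest effects at 1w included Tnfsf18, the T cell ligand GITRL (chromosome 1, 161494657 to 161505290, log2 7.60 ± 0.58, adjusted p = 9.46e-07), with 473 counts over the PQ libraries against 2, a ratio of 229 (95% counting interval 63.1 to 1900). Chl1, a cell adhesion molecule (chromosome 6, 103510584 to 103733038), rose 74.1-fold (log2 6.21 ± 0.46, adjusted p = 7.93e-07). Grem1, a secreted antagonist of bone morphogenetic proteins (chromosome 2, 113748675 to 113758648), rose 70.9-fold (log2 6.15 ± 0.80, adjusted p = 6.14e-05). Kcnt1, a sodium-activated potassium channel (chromosome 2, 25863791 to 25918273, log2 5.80 ± 0.51, adjusted p = 2.69e-06), had 193 counts against 3, a ratio of 62.4 (21 to 305). Xntrpc, a read-through transcript that overlaps Trpc2 (chromosome 7, 102065491 to 102096864, log2 8.50 ± 2.64, adjusted p = 0.0219), had 138 counts against 0, at least 44.6-fold, and its assignment between the overlapping genes is uncertain. Hes2, a transcriptional repressor (chromosome 4, 152158867 to 152162469), fell 28.4-fold (log2 -4.83 ± 0.55, adjusted p = 2.01e-05). Fabp1, a fatty acid binding protein (chromosome 6, 71199879 to 71205034), fell 17.9-fold (log2 -4.16 ± 0.37, adjusted p = 3.52e-06), and Apob, the lipid carrier apolipoprotein B (chromosome 12, 7977629 to 8016839, log2 -4.56 ± 0.94, adjusted p = 0.00164), had 3 counts in PQ against 77, 26.5-fold lower (8.72 to 131). Colq, the collagen tail of acetylcholinesterase (chromosome 14, 31523082 to 31577863), fell 15.5-fold (log2 -3.95 ± 0.31, adjusted p = 1.29e-06). Slc7a10, an amino acid transporter (chromosome 7, 35186095 to 35201116), fell 13.2-fold (log2 -3.72 ± 0.12, adjusted p = 5.34e-09).

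In total 7772 of 15921 genes (48.8%) passed at 1w, 4129 higher and 3643 lower, and 1961 of them changed at least 2-fold, 1151 higher and 810 lower. For 9353 genes (58.7%) the 3 PQ values did not overlap the 3 control values, where chance gives 10%. Of the 45 lists 31 passed, 16 higher and 15 lower, and 7 passed with an estimated correlation. The other lists that did not pass were pericyte (10 genes: 2 rose, 5 fell and 3 did not pass, 2 and 6 adjusted over the list alone, adjusted p = 0.139), mesothelium (11: 3 rose, 1 fell and 7 did not pass, 3 and 1 adjusted over the list alone, adjusted p = 0.339) and basal airway epithelium (10: 4 rose, 0 fell and 6 did not pass, 3 and 0 adjusted over the list alone, adjusted p = 0.341). Of 15 monocyte genes, 2 rose, 5 fell and 8 did not pass, 2 and 5 adjusted over the list alone, adjusted p = 0.768. Of 17 neutrophil genes, 1 rose, 6 fell and 10 did not pass, 1 and 6 adjusted over the list alone, adjusted p = 0.3. Of 10 plasma cell genes, 3 rose, 6 fell and 1 did not pass, 3 and 6 adjusted over the list alone, adjusted p = 0.576. Of 20 genes of lipid synthesis and cholesterol, 7 rose, 3 fell and 10 did not pass, 7 and 3 adjusted over the list alone, adjusted p = 0.599. Of 16 immediate early genes, 8 rose, 5 fell and 3 did not pass, 8 and 5 adjusted over the list alone, adjusted p = 0.599. None of 14 cardiac muscle genes passed in edgeR (0 at an unadjusted p under 0.05 and 0 by DESeq2), and 1 of 11 adipocyte genes fell, 0 and 1 adjusted over the list alone (adjusted p = 0.799 and 0.589). The club and mucous list and the antioxidant list had a median and mean above 0 where camera ranked them lower, and the circadian and adipocyte lists had a median above 0 and a mean below it. The call of Xntrpc was lost without any 1 of the control 1w libraries, without PQ 1w replicate 1 and in the limma fit of FPKM with no expression filter, where Sftpc was lost too. With a library left out, effects ranged from log2 5.54 to 6.76 for Grem1 and reached 7.40 for Chl1, 6.65 for Kcnt1, -7.71 for Apob and -4.92 for Fabp1. Without control 1w replicate 2 the TGF-beta, dendritic cell, chemokine and erythroid lists did not pass, without PQ 1w replicate 1 the dendritic cell and complex I lists, and without PQ 1w replicate 2 the erythroid list. The median of the club and mucous list went from -0.33 to 1.289 with a library left out. Ager passed in DESeq2 and in a fit of the 1w libraries alone. Each gene said to rise or fall at 1w had all 3 PQ libraries beyond all 3 controls, as did the mean level of each list that passed except the club and ciliated lists.

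**Figure D2:**
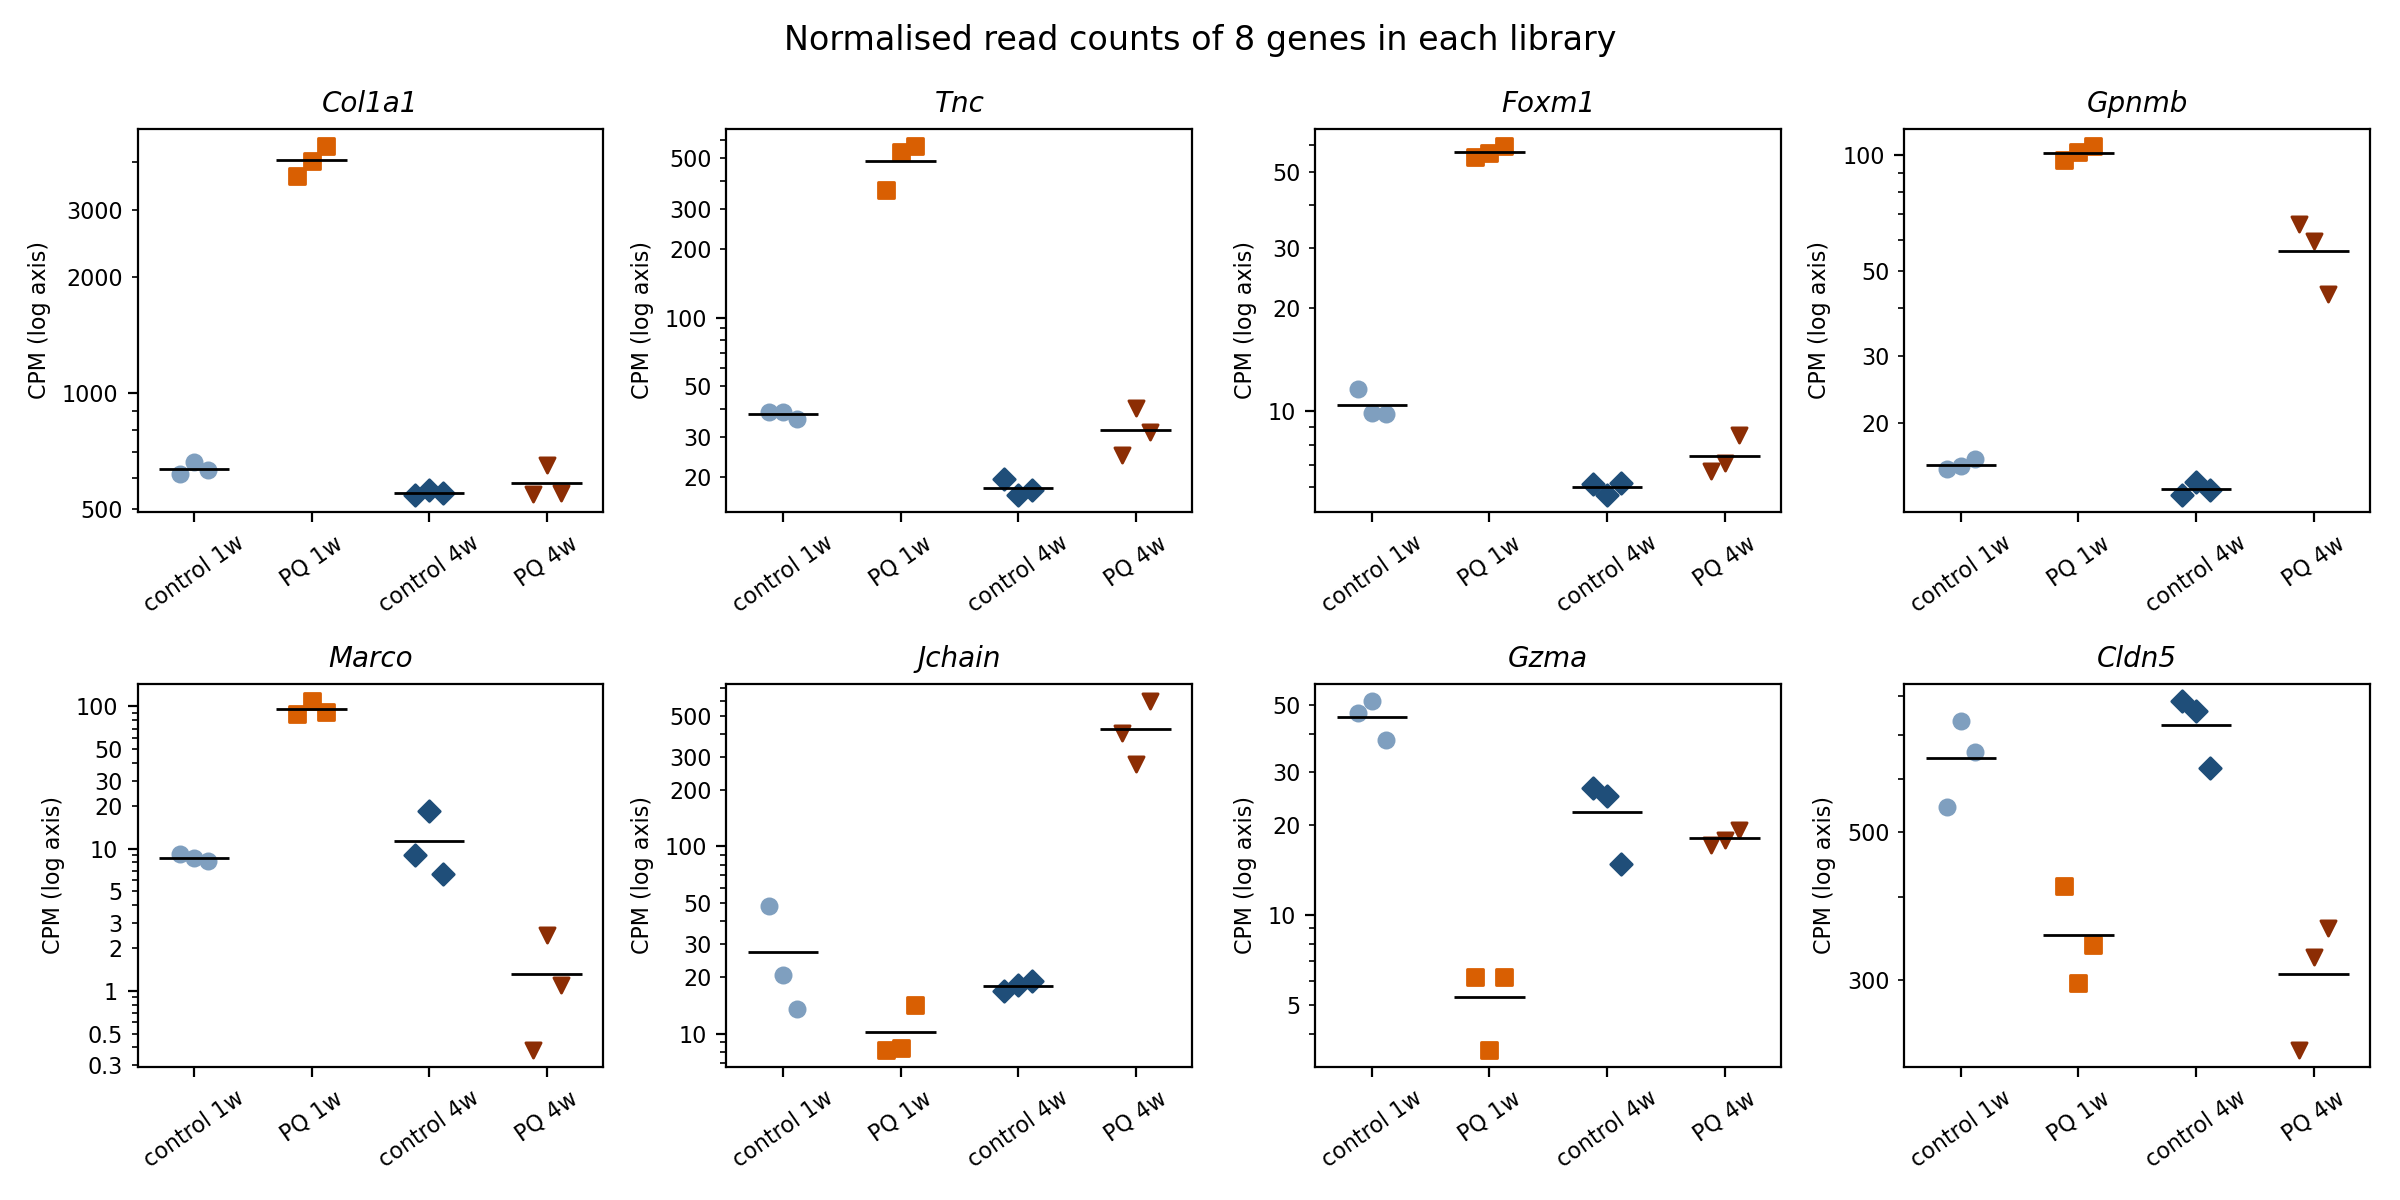
CPM (log axis) of Col1a1, Tnc, Foxm1, Gpnmb, Marco, Jchain, Gzma and Cldn5 in each of the 12 libraries by group, with lines at the group means. Col1a1 was at 4031 CPM in PQ 1w and 582 CPM in PQ 4w.

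At 4w, macrophage, dendritic cell, T cell and plasma cell transcripts rose. Gpnmb rose 4.17-fold (log2 2.06 ± 0.13, adjusted p = 1.88e-05), from 13.5 ± 0.538 to 56.3 ± 11.6 CPM, and Cd68 rose 2.19-fold (log2 1.13 ± 0.08, adjusted p = 8.03e-05). Of 20 monocyte-derived and tissue macrophage genes, 13 rose, 0 fell and 7 did not pass (13 and 1 adjusted over the list alone). Median log2 was 1.12, with adjusted p = 9.86e-35, 0.000402 with an estimated correlation. C1qb, a chain of complement C1q made by macrophages, rose 3.02-fold (log2 1.59 ± 0.15, adjusted p = 0.000247), C3ar1, the receptor of the C3a fragment, rose 3.09-fold (log2 1.63 ± 0.15, adjusted p = 0.000247), and of 21 complement genes, 11 rose, 0 fell and 10 did not pass (11 and 0 adjusted over the list alone). Median log2 was 0.39, with adjusted p = 1.13e-13, 0.0416 with an estimated correlation. Xcr1 and Flt3, receptors of dendritic cells, rose 2.64-fold (adjusted p = 0.000347) and 2.91-fold (adjusted p = 0.000574). Of 15 dendritic cell genes, 10 rose, 0 fell and 5 did not pass (12 and 1 adjusted over the list alone). Median log2 was 1.15, with adjusted p = 1.32e-12, 0.0416 with an estimated correlation. Jchain, the joining chain of secreted immunoglobulin (chromosome 5, 88519809 to 88527897), rose 23.6-fold (log2 4.56 ± 0.43, adjusted p = 0.000247), from 18.1 ± 1.15 to 426 ± 162 CPM. Of 10 plasma cell genes, 5 rose, 0 fell and 5 did not pass (5 and 0 adjusted over the list alone). Median log2 was 0.76, with adjusted p = 0.000336, 0.348 with an estimated correlation. Foxp3, the transcription factor of regulatory T cells, and Cd4, the helper T cell coreceptor, rose 3.43-fold (adjusted p = 0.00293) and 2.67-fold (adjusted p = 0.00293). Of 19 T cell genes, 10 rose, 0 fell and 9 did not pass (15 and 0 adjusted over the list alone). Median log2 was 0.86, with adjusted p = 1.11e-09, 0.4 with an estimated correlation. Of 12 lymphoid follicle genes, 3 rose, 0 fell and 9 did not pass (4 and 0 adjusted over the list alone). Median log2 was 0.54, with adjusted p = 0.0164, 0.47 with an estimated correlation. The follicle list was at log2 0.274, 0.026 and 0.86 in PQ 4w replicates 1 to 3, relative to the 6 controls, and did not pass without replicate 3 (2 rose and 1 fell, median log2 0.189).

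Interferon-induced genes rose at 4w, most in replicate 3. Mx1, a GTPase of the antiviral response, rose 4.58-fold (log2 2.20 ± 0.40, adjusted p = 0.0059), and Oas2, an antiviral oligoadenylate synthetase, rose 2.12-fold (log2 1.09 ± 0.22, adjusted p = 0.00995). Of 25 interferon-induced genes, 20 rose, 0 fell and 5 did not pass (23 and 0 adjusted over the list alone). Median log2 was 1.09, with adjusted p = 1.46e-13, 0.4 with an estimated correlation. The mean level of this list relative to the controls was log2 0.341, 0.427 and 1.53 in PQ 4w replicates 1 to 3. The T cell list was at 0.44, 0.065 and 0.953 in the same libraries. Replicate 3 was also the PQ 4w library in which the club and mucous list was lowest (log2 -0.653, against 1.81 and 2.39). Without replicate 3, 15 of 25 interferon-induced genes, 9 of 19 T cell genes, 13 of 20 macrophage genes and 6 of 10 plasma cell genes rose. The median log2 was then 0.498 for the interferon-induced list and 0.519 for the T cell list, both still passing, and Mx1 was at log2 1.49. Of 26 inflammatory chemokines and cytokines, 8 rose, 0 fell and 18 did not pass (9 and 2 adjusted over the list alone). Median log2 was 0.64, with adjusted p = 0.000503, 0.348 with an estimated correlation. Of 29 proliferation genes, 12 rose, 0 fell and 17 did not pass (22 and 0 adjusted over the list alone). Median log2 was 0.45, with adjusted p = 1.82e-10, 0.348 with an estimated correlation. Top2a, a topoisomerase of dividing cells, and Aurkb, a mitotic kinase, rose 1.85-fold (adjusted p = 0.00968) and 1.76-fold (adjusted p = 0.00888), and Mki67 rose 1.93-fold (adjusted p = 0.015).

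Endothelial transcripts fell at 4w. Cldn5, the tight junction protein claudin-5 (chromosome 16, 18776847 to 18778262), fell 2.36-fold (log2 -1.24 ± 0.17, adjusted p = 0.0016), from 723 ± 87.1 to 307 ± 63.7 CPM. Esam, an endothelial adhesion molecule, fell 1.66-fold (log2 -0.73 ± 0.11, adjusted p = 0.00235). Apln, the peptide apelin, fell 2.96-fold (log2 -1.56 ± 0.24, adjusted p = 0.00292), and Tbx3, a transcription factor of capillaries, fell 1.57-fold (log2 -0.65 ± 0.10, adjusted p = 0.00207). Of 18 genes of all endothelium, 2 rose, 13 fell and 3 did not pass (2 and 16 adjusted over the list alone). Median log2 was -0.43, with adjusted p = 7.71e-10, 0.303 with an estimated correlation. Of 18 capillary endothelium genes, 0 rose, 10 fell and 8 did not pass (0 and 12 adjusted over the list alone). Median log2 was -0.68, with adjusted p = 1.39e-10, 0.288 with an estimated correlation. PQ 4w replicate 1 was lower than replicates 2 and 3 in the capillary list (log2 -1.121 against -0.453 and -0.453, relative to the 6 controls), in all endothelium (-0.701 against -0.312 and -0.323) and in alveolar type 1 epithelium (-1.096 against -0.4 and -0.339). Without replicate 1 these lists still passed, at median log2 -0.511, -0.32 and -0.148. Cdkn1a fell to 0.377 times the control (adjusted p = 0.000919), from 280.4 ± 71.7 to 106 ± 16.1 CPM. Of 16 alveolar type 1 epithelium genes, 0 rose, 3 fell and 13 did not pass (0 and 5 adjusted over the list alone). Median log2 was -0.32, with adjusted p = 1.28e-05, 0.47 with an estimated correlation. Ager was at 0.693 times the control and did not pass (adjusted p = 0.0687). Of 23 genes of mitochondrial complex I, 0 rose, 7 fell and 16 did not pass (0 and 12 adjusted over the list alone). Median log2 was -0.20, with adjusted p = 8.57e-06, 0.47 with an estimated correlation. Of 17 neutrophil genes, 1 rose, 8 fell and 8 did not pass (2 and 11 adjusted over the list alone). Median log2 was -1.38, with adjusted p = 0.000637, 0.47 with an estimated correlation. Of 29 antioxidant and NRF2 targets, 0 rose, 7 fell and 22 did not pass (0 and 9 adjusted over the list alone). Median log2 was -0.23, with adjusted p = 0.00339, 0.509 with an estimated correlation. Of 23 xenobiotic metabolism genes, 0 rose, 5 fell and 18 did not pass (0 and 6 adjusted over the list alone). Median log2 was -0.27, with adjusted p = 0.00461, 0.49 with an estimated correlation. The xenobiotic and antioxidant lists did not pass without PQ 4w replicate 3, whose airway lists were low (median log2 -0.103 and -0.183). The xenobiotic list was at log2 0.19, 0.405 and -0.37 in PQ 4w and at 0.184, 0.519 and 0.37 in control 4w.

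Few matrix genes passed at 4w. Col1a1 was at 1.06 times the control (adjusted p = 0.59), from 550.5 ± 8.94 to 582 ± 59.2 CPM. Col3a1 rose 1.32-fold (log2 0.40 ± 0.10, adjusted p = 0.0227) and Fn1 rose 1.75-fold (log2 0.80 ± 0.18, adjusted p = 0.0144). Timp1, Acta2 and Tgfb1 did not pass (log2 0.34 ± 0.19, adjusted p = 0.269, log2 -0.39 ± 0.17, adjusted p = 0.164 and log2 -0.13 ± 0.09, adjusted p = 0.384). Of 15 interstitial collagen genes, 3 rose, 0 fell and 12 did not pass (5 and 0 adjusted over the list alone). Median log2 was 0.09, with adjusted p = 0.0397, 0.47 with an estimated correlation. Of 25 matrix glycoproteins and proteoglycans, 5 rose, 1 fell and 19 did not pass (6 and 1 adjusted over the list alone). Median log2 was 0.23, with adjusted p = 0.0404, 0.47 with an estimated correlation. Of 23 matrix proteases and inhibitors, 6 rose, 3 fell and 14 did not pass (8 and 4 adjusted over the list alone). Median log2 was 0.24, with adjusted p = 0.00251, 0.149 with an estimated correlation. The collagen list did not pass without control 4w replicate 2 or PQ 4w replicate 2 or 3, nor the glycoprotein list without control replicate 1 or 3 or PQ replicate 2 or 3. With all libraries the collagen processing and crosslinking list did not pass: 2 rose, 5 fell and 10 did not pass, 3 and 5 adjusted over the list alone, adjusted p = 0.113. Of 21 basement membrane genes, 1 rose, 0 fell and 20 did not pass, 0 and 0 adjusted over the list alone, adjusted p = 0.854. Of 24 genes of TGF-beta family signalling, 3 rose, 4 fell and 17 did not pass, 4 and 5 adjusted over the list alone, adjusted p = 0.556. Of 14 alveolar fibroblast genes, 1 rose, 4 fell and 9 did not pass (2 and 4 adjusted over the list alone). Median log2 was -0.18, with adjusted p = 0.0248, 0.404 with an estimated correlation. This list did not pass without control replicate 3 or PQ replicate 2. Sftpc did not pass (log2 -0.01 ± 0.11, adjusted p = 0.981), and of 17 alveolar type 2 epithelium genes, 5 rose, 0 fell and 12 did not pass (6 and 0 adjusted over the list alone). Median log2 was 0.23, with adjusted p = 0.00251, 0.473 with an estimated correlation. That list did not pass without PQ 4w replicate 3, with 1 gene higher and a median log2 of 0.146.

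Sprr2a2 and Sprr2a3, paralogs that code for cornified envelope proteins (chromosome 3, 92250647 to 92257304, and chromosome 3, 92285304 to 92289264), had 193 and 142 counts in PQ 4w against 2 each in control 4w, ratios of 93.5 (25.5 to 777) and 68.8 (18.7 to 573), with log2 6.30 ± 1.28, adjusted p = 0.00999, and log2 5.87 ± 1.18, adjusted p = 0.00938. These paralogs have close sequences, so the division of reads between them is uncertain. In PQ 4w replicates 1 to 3 Sprr2a2 was at 8.52, 1.80 and 0.329 CPM and Sprr2a3 at 4.67, 2.93 and 0.275 CPM, a spread that the counting intervals leave out. Without replicate 1 their effects were log2 4.57 and 5.15, and without control 4w replicate 2 that of Sprr2a3 was 8.55. Of 10 basal airway epithelium genes, 4 rose, 0 fell and 6 did not pass (7 and 0 adjusted over the list alone). Median log2 was 2.31, with adjusted p = 0.00112, 0.404 with an estimated correlation. This median was 1.81 with the gene without control counts at its bound and 1.52 without PQ 4w replicate 1. Kng2, a kininogen (chromosome 16, 22985852 to 23029101), rose 26.9-fold (log2 4.75 ± 0.64, adjusted p = 0.0014). Chil4, a chitinase-like protein with the close paralog Chil3 (chromosome 3, 106201491 to 106219479, log2 8.39 ± 2.34, adjusted p = 0.0373), was at 179 CPM in replicate 2 and under 1 CPM in the other two, and did not pass without replicate 2 (log2 1.97, adjusted p = 0.429, 0.0097 to 0.429 over all alternatives). Marco, a scavenger receptor of alveolar macrophages (chromosome 1, 120474538 to 120505024), fell 8.65-fold (log2 -3.11 ± 0.46, adjusted p = 0.0021), and was at log2 -3.92 without PQ 4w replicate 2. Fabp1 and Apob fell 4.81-fold (log2 -2.27 ± 0.29, adjusted p = 0.00122) and 5.43-fold (log2 -2.44 ± 0.65, adjusted p = 0.0301), and Apob was at log2 -1.86 without PQ 4w replicate 1 and -3.41 without replicate 3. Krt79, a keratin (chromosome 15, 101929332 to 101940324), fell 5.15-fold (log2 -2.36 ± 0.55, adjusted p = 0.0172), and Nlrp12, a regulator of inflammation (chromosome 7, 3218643 to 3249771), fell 4.78-fold (log2 -2.26 ± 0.60, adjusted p = 0.0296) and was at log2 -1.53 without control 4w replicate 2. Among 18 alveolar macrophage genes, 3 rose, 4 fell and 11 did not pass, 3 and 5 adjusted over the list alone, adjusted p = 0.415.

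In total 1932 genes (12.1%) passed at 4w, 915 higher and 1017 lower, of which 388 changed at least 2-fold, 294 higher and 94 lower. A fit of only the 6 libraries at 4w passed 746. Non-overlapping values were found for 4961 genes (31.2%, chance 10%). Of the 45 lists 24 passed, and 3 passed with an estimated correlation. Of these 24, 17 passed without PQ 4w replicate 3, as did 4 others. Of 14 cardiac muscle genes, 0 rose, 0 fell and 14 did not pass (0 and 0 adjusted over the list alone). Median log2 was -1.07, with adjusted p = 0.0125, 0.656 with an estimated correlation, although edgeR called 0 members (1 at an unadjusted p under 0.05, 0 by DESeq2). This list was at log2 0.736, 2.37 and 1.96 in control 4w and at 0.726, 1.54 and -1.34 in PQ 4w, and did not pass without PQ 4w replicate 3 (median log2 -0.622) or control 4w replicate 2. Of 17 circadian clock genes, 7 rose, 1 fell and 9 did not pass (7 and 4 adjusted over the list alone). Median log2 was 0.29, with adjusted p = 0.0153, 0.404 with an estimated correlation, and this list did not pass without control 4w replicate 2. The remaining lists did not pass: smooth muscle and myofibroblast (0 rose, 1 fell and 12 did not pass, 0 and 0 adjusted over the list alone, adjusted p = 0.0916), adventitial fibroblast (3 rose, 3 fell and 6 did not pass, 4 and 3 adjusted over the list alone, adjusted p = 0.415), pericyte (0 rose, 2 fell and 8 did not pass, 0 and 4 adjusted over the list alone, adjusted p = 0.129) and mesothelium (0 rose, 1 fell and 10 did not pass, 0 and 0 adjusted over the list alone, adjusted p = 0.072). In the transitional alveolar epithelium list 5 rose, 1 fell and 10 did not pass, 5 and 2 adjusted over the list alone, adjusted p = 0.072, and in the club and mucous airway epithelium list 2 rose, 1 fell and 12 did not pass, 2 and 3 adjusted over the list alone, adjusted p = 0.558. No ciliated airway epithelium, NK cell, B cell or erythroid gene passed in edgeR, over all genes tested or adjusted over the list alone (0, 1, 4 and 2 at an unadjusted p under 0.05, and 0, 1, 2 and 0 by DESeq2, list adjusted p = 0.186, 0.949, 0.566 and 0.072). Without PQ 4w replicate 3, whose airway lists were low, 9 of 20 ciliated genes rose and 0 fell (median log2 0.577 against 0.289 with all libraries, the list then passing), and 0 of 16 B cell genes rose and 4 fell (median log2 -0.363). The mesothelium and transitional lists passed as well, at median log2 -0.568 and 0.381.

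Among monocyte genes 1 rose, 0 fell and 14 did not pass, 0 and 0 adjusted over the list alone, adjusted p = 0.675. Among p53 targets 4 rose, 4 fell and 14 did not pass, 5 and 4 adjusted over the list alone, adjusted p = 0.976. For lipid synthesis and cholesterol 1 rose, 0 fell and 19 did not pass, 0 and 0 adjusted over the list alone, adjusted p = 0.92. For glycolysis and hypoxia 2 rose, 1 fell and 17 did not pass, 3 and 1 adjusted over the list alone, adjusted p = 0.152. For endoplasmic reticulum stress 1 rose, 2 fell and 17 did not pass, 1 and 3 adjusted over the list alone, adjusted p = 0.415. Among immediate early genes 2 rose, 3 fell and 11 did not pass, 2 and 3 adjusted over the list alone, adjusted p = 0.593, and among adipocyte genes 0 rose, 1 fell and 10 did not pass, 0 and 1 adjusted over the list alone, adjusted p = 0.0715. Camera ranked the club and mucous, p53 and immediate early lists lower although their median and mean were above 0, and the lipid list higher although both were below 0. The alveolar macrophage list had a median of log2 0.05 and a mean of -0.43, and the TGF-beta list one of 0.01 and -0.07, both ranked lower, and the basement membrane list one of 0.01 and -0.02, ranked higher. The calls of Apob and Nlrp12 were lost without control 4w replicate 1 or 2 or PQ 4w replicate 1 or 2, that of Col3a1 without control replicate 1 or 3 or PQ replicate 2 or 3, and that of Fn1 without control replicate 1 or 2. Oas2, Krt79 and Sprr2a2 were lost without control replicate 1, Mki67 without control replicate 3, and Chil4 without any 1 control. Aurkb was lost in a fit of the 4w libraries alone, and Sprr2a3 in the limma fit with no filter. Ager and Tgfb1 passed without PQ replicate 3, Acta2 without PQ replicate 2 and Timp1 without control replicate 2. Each gene said to rise or fall at 4w had all 3 PQ libraries beyond all 3 controls. Among lists that passed, the mean levels of the collagen, neutrophil, lymphoid follicle, antioxidant, xenobiotic, circadian and cardiac lists overlapped between PQ and control. With 1 library left out in turn, the median log2 ranged from 0.078 to 0.182 for collagens, 0.14 to 0.361 for matrix glycoproteins, -0.245 to -0.122 for alveolar fibroblast, -0.272 to -0.095 for antioxidant, 0.184 to 0.39 for circadian, 0.189 to 0.837 for lymphoid follicle and -1.77 to -0.622 for cardiac genes.

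**Figure D3:**
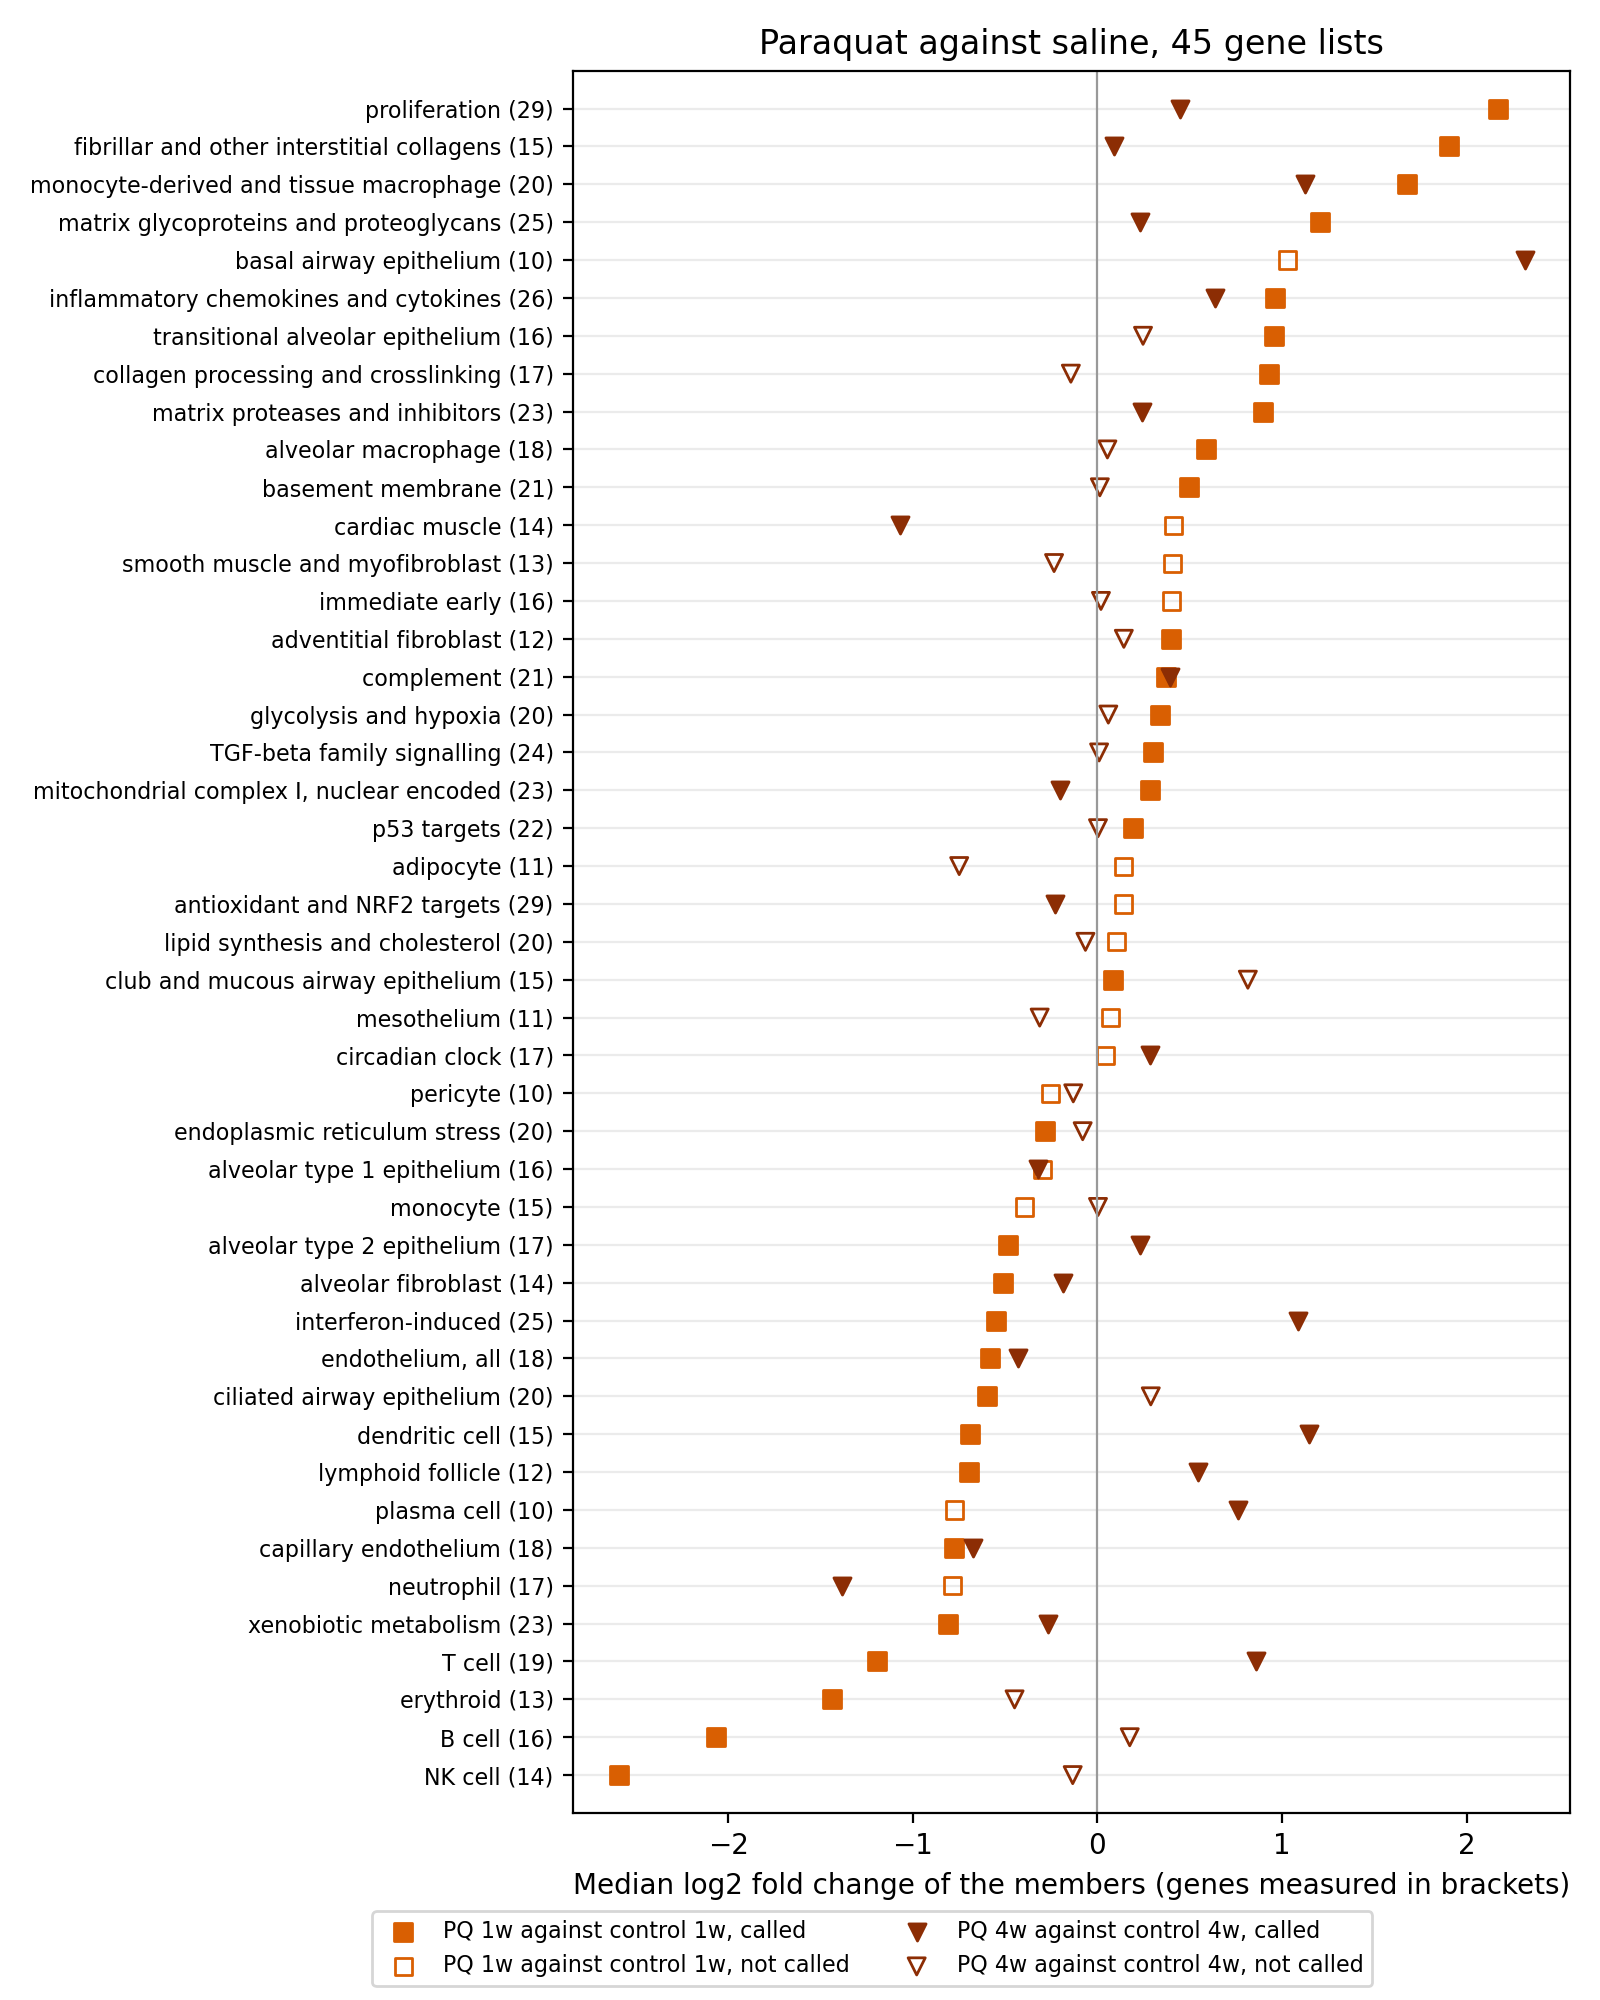
Median log2 fold of the measured genes of each of the 45 lists, squares for PQ 1w and triangles for PQ 4w against their controls, filled where camera adjusted p was under 0.05. Proliferation was at 2.17 at 1w and NK cell genes at -2.60.

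The PQ effect differed between the times for lymphocyte, matrix and macrophage genes. Jchain had the largest gain from 1w to 4w (log2 5.98 ± 0.60, adjusted p = 5.37e-05), followed by Cd207, the Langerhans cell lectin langerin (log2 4.85 ± 0.44, adjusted p = 3.25e-05). Gbp10, an interferon-induced GTPase, Ms4a4c, a membrane protein of monocytes, and Dnase1l3, a nuclease of dendritic cells and macrophages, also gained (log2 4.22 ± 1.12, adjusted p = 0.0136, log2 3.85 ± 0.79, adjusted p = 0.00322 and log2 3.79 ± 0.83, adjusted p = 0.00497). Replicate 3 carried much of these gains: in PQ 4w replicates 1 to 3 Gbp10 was at 2.03, 1.13 and 12.6 CPM, Ms4a4c at 5.72, 6.24 and 25.1 CPM and Dnase1l3 at 7.53, 4.05 and 24.3 CPM. Without it they passed at log2 2.48, 2.80 and 2.73. Marco rose at 1w (11.2-fold, adjusted p = 6.8e-06) and fell at 4w, a difference of log2 -6.60 ± 0.56, adjusted p = 2.2e-05. The effect was lower at 4w for Tnfsf18 (log2 -6.58 ± 1.24, adjusted p = 0.00201), for Hmga2, a chromatin protein of growing tissue (log2 -5.74 ± 1.24, adjusted p = 0.00455), and for Grem1 (log2 -5.33 ± 1.54, adjusted p = 0.0201). Vsig4, a complement receptor of resident macrophages, differed by log2 -5.03 ± 1.34, adjusted p = 0.0134. The differences of Marco, Tnfsf18, Grem1 and Vsig4 were log2 -7.40, -7.86, -6.03 and -6.38 without PQ 4w replicate 2, and without control 1w replicate 1 that of Jchain was 5.29 and those of Grem1 and Vsig4 were -5.94 and -6.56.

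Lists differed in both directions between the times. Effects on all 14 NK cell genes and all 19 T cell genes were higher at 4w (14 higher and 0 lower, 14 and 0 adjusted over the list alone, median log2 2.42, adjusted p = 8.82e-19, 0.0427 with an estimated correlation, and 19 higher and 0 lower, 19 and 0 adjusted over the list alone, median log2 2.06, adjusted p = 3.28e-16, 0.139 with an estimated correlation). B cell genes gained as well (13 higher and 0 lower, 16 and 0 adjusted over the list alone, median log2 2.15, adjusted p = 4.83e-09, 0.297 with an estimated correlation), as did dendritic cell genes (10 higher and 1 lower, 11 and 1 adjusted over the list alone, median log2 1.76, adjusted p = 5.92e-09, 0.0427 with an estimated correlation), interferon-induced genes (21 higher and 0 lower, 21 and 0 adjusted over the list alone, median log2 1.58, adjusted p = 1.33e-10, 0.32 with an estimated correlation, and a median of 0.962 without PQ 4w replicate 3) and alveolar type 2 epithelium genes (10 higher and 0 lower, 12 and 0 adjusted over the list alone, median log2 0.64, adjusted p = 1.16e-08, 0.165 with an estimated correlation). Collagen effects were lower at 4w (0 higher and 14 lower, 0 and 14 adjusted over the list alone, median log2 -1.71, adjusted p = 2.86e-34, 0.00191 with an estimated correlation), as were those on proliferation (0 higher and 29 lower, 0 and 29 adjusted over the list alone, median log2 -1.54, adjusted p = 2.6e-28, 0.0427 with an estimated correlation), collagen processing and crosslinking (1 higher and 15 lower, 1 and 15 adjusted over the list alone, median log2 -0.88, adjusted p = 9.68e-15, 0.0137 with an estimated correlation) and matrix glycoproteins and proteoglycans (1 higher and 19 lower, 2 and 20 adjusted over the list alone, median log2 -1.10, adjusted p = 2.21e-14, 0.0158 with an estimated correlation). Effects on the monocyte-derived and tissue macrophage list were lower too (2 higher and 8 lower, 2 and 12 adjusted over the list alone, median log2 -0.49, adjusted p = 0.00063, 0.0859 with an estimated correlation). No difference was called for endothelial genes, with 0 of 18 passing in edgeR (2 at an unadjusted p under 0.05, 2 by DESeq2, list adjusted p = 0.548). The capillary endothelium and complement lists did not pass (adjusted p = 0.556 and 0.594), each with a median above 0, a mean below 0 and a higher camera rank. The interaction term passed for 5092 genes (32.0%), 2250 higher and 2842 lower, and for 29 lists, 13 higher and 16 lower, 7 with an estimated correlation. Gbp10 was not called in the limma fit with no filter, and Grem1 and Vsig4 not without control 4w replicate 2 (log2 -4.37 and -4.26). Grem1 was at -4.73 without PQ 1w replicate 2.

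Some genes passed at both times. Higher at both were 493 genes, among them Gpnmb, Cd68, Fn1 and Mki67, where independent lists would share 237.3, and lower at both were 523, among them Fabp1, Apob and Cdkn1a, where independent lists would share 232.7. Opposite calls numbered 256, of which 133 were lower at 1w and higher at 4w and 123 the reverse, with Marco among the latter (209.4 and 263.8 for independent lists). The 2 comparisons share no library. Log2 effects of all tested genes correlated with Pearson r of 0.361 and Spearman 0.219, and genes are not independent replicates. Of genes higher at 1w, 3513 (85.1%) did not pass at 4w, and of these the effect differed for 2176. Of genes lower at 1w, 2987 (82%) did not pass at 4w, with a differing effect for 1702. The median log2 effect of genes higher at 1w was 0.58 at 1w and 0.06 at 4w, and that of genes lower at 1w -0.55 and -0.07.

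**Figure D4:**
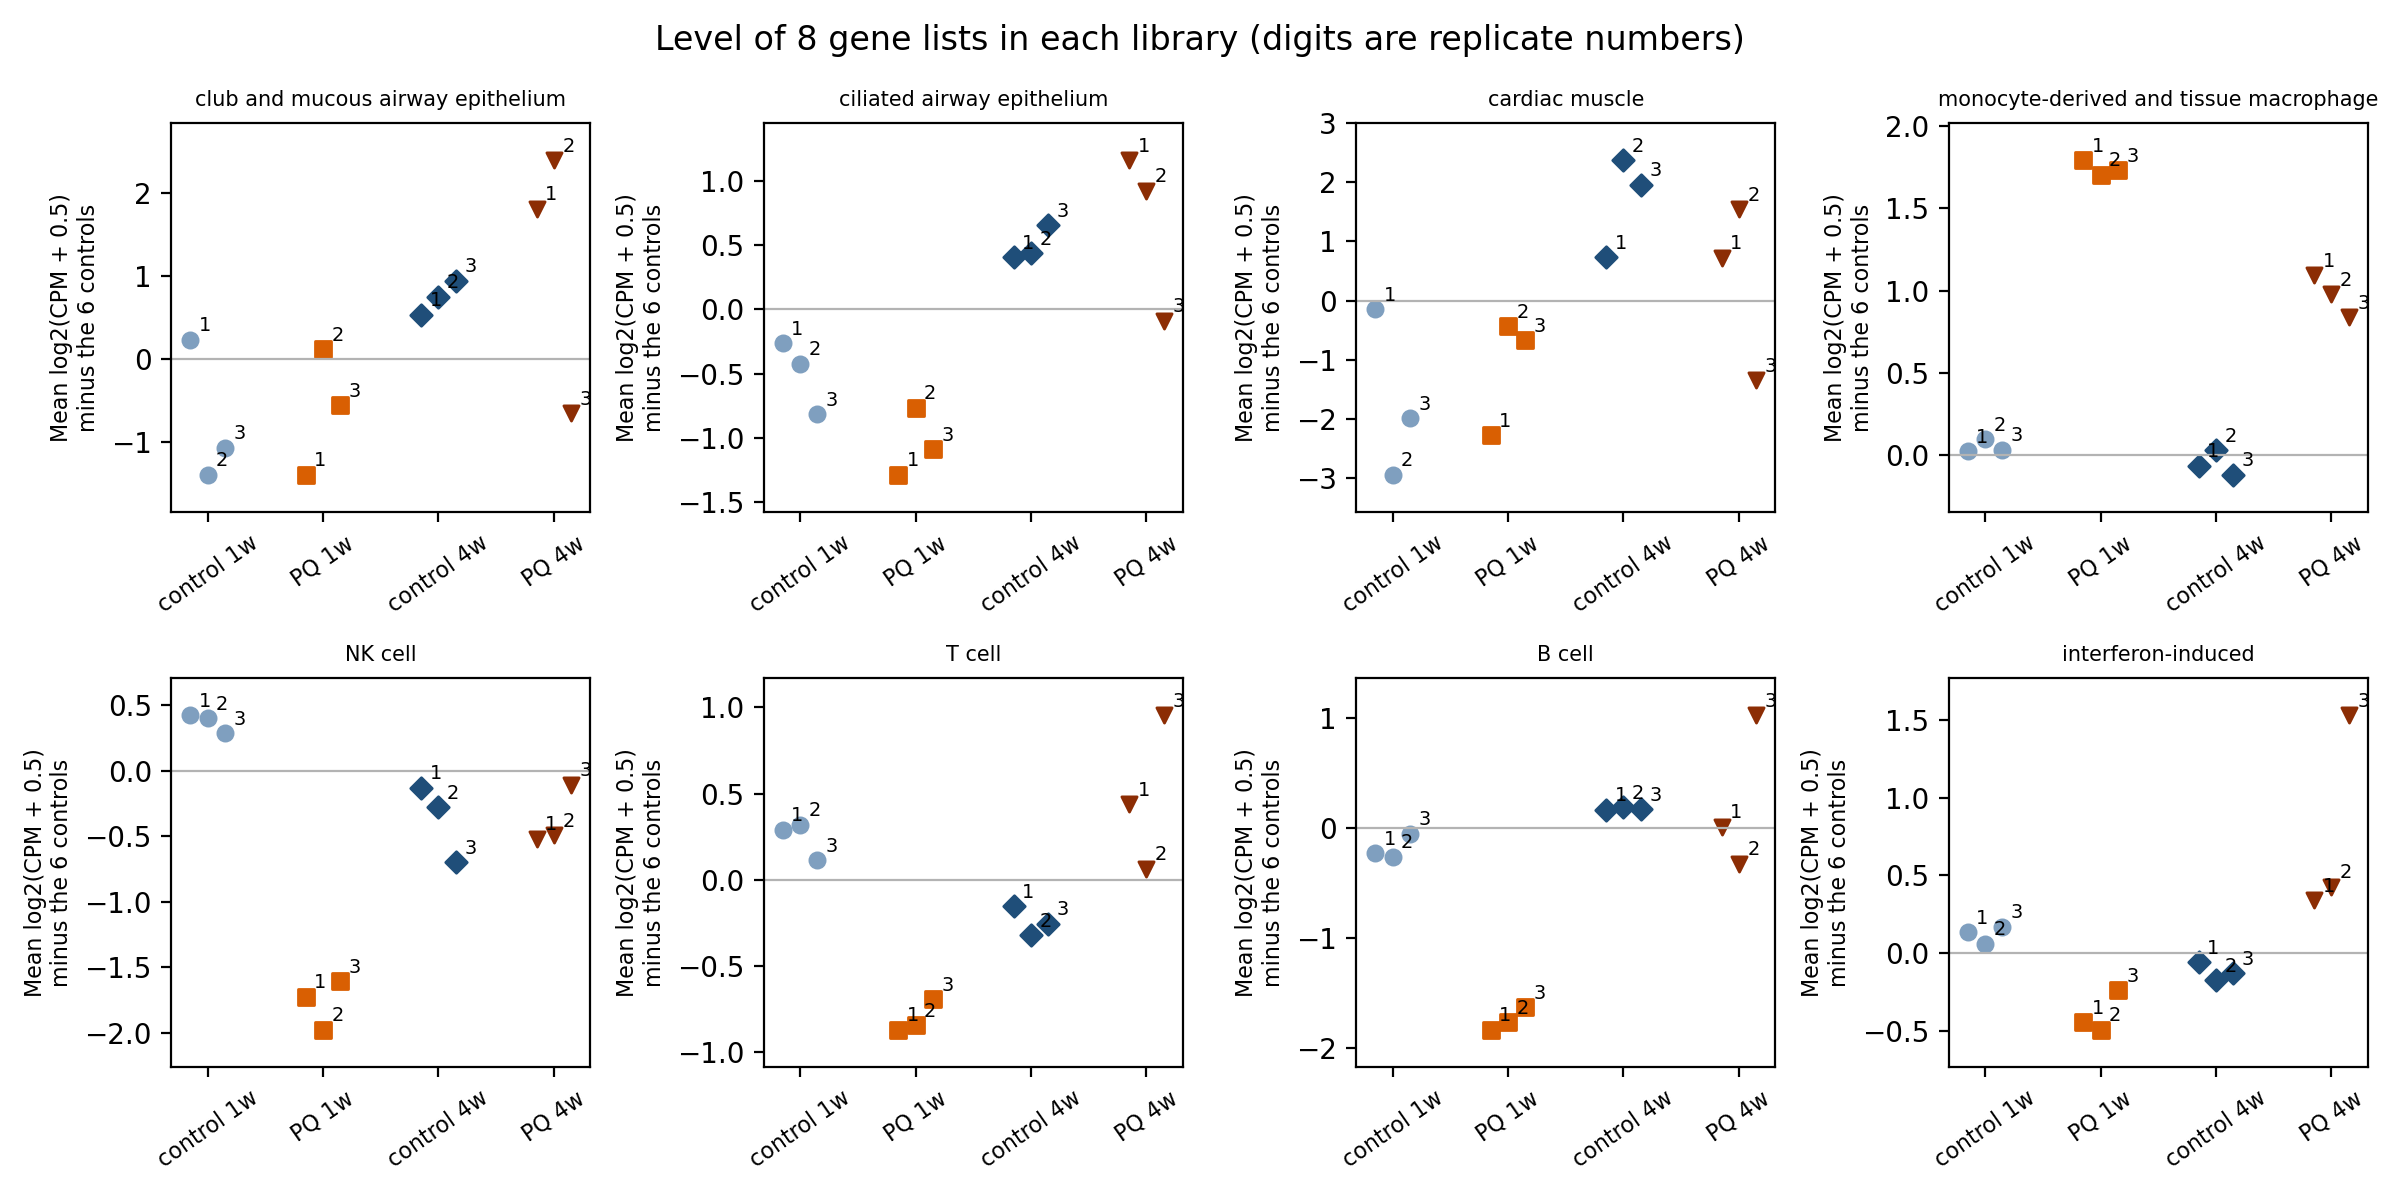
Mean level of selected gene lists in each library (log2 relative to the 6 control libraries), by group, 1 point per library. The interferon-induced list was at 0.341, 0.427 and 1.53 in PQ 4w, and the cardiac muscle list at 0.736, 2.37 and 1.96 in control 4w.

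Between PQ 4w and PQ 1w, Jchain was higher 41.5-fold (log2 5.38 ± 0.46, adjusted p = 2.23e-06), Cd207 17.1-fold (log2 4.09 ± 0.34, adjusted p = 2.06e-06) and Dnase1l3 14.8-fold (log2 3.89 ± 0.59, adjusted p = 0.00017). Izumo1r, the folate receptor of regulatory T cells, and Hes2 were higher 13.2-fold (log2 3.72 ± 0.64, adjusted p = 0.000424) and 12.6-fold (log2 3.65 ± 0.59, adjusted p = 0.000285). Dnase1l3 and Izumo1r were at log2 2.82 and 2.86 without PQ 4w replicate 3. Marco was lower 72.9-fold (log2 -6.19 ± 0.43, adjusted p = 5.12e-07), as were Lrrc15, a membrane protein of myofibroblasts (32.4-fold, log2 -5.02 ± 0.51, adjusted p = 9.27e-06), A2m, the protease inhibitor alpha-2-macroglobulin (27.3-fold, log2 -4.77 ± 0.36, adjusted p = 7.96e-07), Tnfsf18 (30.4-fold, log2 -4.92 ± 0.43, adjusted p = 2.7e-06) and Grem1 (23.8-fold, log2 -4.57 ± 0.67, adjusted p = 0.000142). With PQ 4w replicate 2 left out Marco, Tnfsf18 and Grem1 were at log2 -7.01, -6.21 and -5.27, and with PQ 1w replicate 2 left out Grem1 was at -3.97. Proliferation and collagen genes were all lower (0 higher and 29 lower, 0 and 29 adjusted over the list alone, median log2 -2.55, adjusted p = 4.69e-54, 0.00911 with an estimated correlation, and 0 higher and 15 lower, 0 and 15 adjusted over the list alone, median log2 -2.31, adjusted p = 6.36e-43, 0.000644 with an estimated correlation). The xenobiotic metabolism list was higher (19 higher and 1 lower, 19 and 1 adjusted over the list alone, median log2 1.56, adjusted p = 4.28e-14, 0.122 with an estimated correlation), as were B cell genes (16 higher and 0 lower, 16 and 0 adjusted over the list alone, median log2 2.44, adjusted p = 1.67e-09, 0.285 with an estimated correlation), T cell genes (19 higher and 0 lower, 19 and 0 adjusted over the list alone, median log2 1.55, adjusted p = 7.64e-08, 0.285 with an estimated correlation) and NK cell genes (14 higher and 0 lower, 14 and 0 adjusted over the list alone, median log2 1.66, adjusted p = 2.64e-07, 0.22 with an estimated correlation). The ciliated airway epithelium and club and mucous airway epithelium lists were higher too (19 higher and 0 lower, 20 and 0 adjusted over the list alone, median log2 1.87, adjusted p = 1.62e-09, 0.295 with an estimated correlation, and 10 higher and 0 lower, 10 and 0 adjusted over the list alone, median log2 2.09, adjusted p = 3.75e-06, 0.307 with an estimated correlation), in libraries with a higher Scgb1a1 share. Scgb1a1 is itself in the club and mucous list, so its share is not independent of that list. The median of the club and mucous list went from 1.528 to 2.718 with a library left out. In total 8684 genes (54.5%) passed, 4254 higher and 4430 lower, with non-overlapping values for 9742 (61.2%, chance 10%), and 29 lists passed, 6 with an estimated correlation. The antioxidant and adipocyte lists ranked higher by camera with a median and mean below 0. This comparison includes any effect of age.

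The saline controls themselves differed between 4w and 1w. Muscle transcripts were higher in control 4w: Nppa, the atrial natriuretic peptide, 25.4-fold (log2 4.67 ± 1.24, adjusted p = 0.0385), from 2.05 ± 2.88 to 52.2 ± 41.6 CPM, Ckm, muscle creatine kinase, 15.9-fold (log2 3.99 ± 0.77, adjusted p = 0.0193), and Mb, myoglobin, 15.5-fold (log2 3.96 ± 1.00, adjusted p = 0.0343). Hfe2, a muscle-expressed regulator of iron, and Eef1a2, a muscle elongation factor, were higher 15.0-fold (adjusted p = 0.0238) and 14.9-fold (adjusted p = 0.0317). The cardiac muscle list of 14 was higher (13 higher and 0 lower, 14 and 0 adjusted over the list alone, median log2 3.22, adjusted p = 1.89e-11, 0.255 with an estimated correlation). Krt14, a basal cell keratin, was lower 8.74-fold (log2 -3.13 ± 0.73, adjusted p = 0.0277), as were Apol11b, an apolipoprotein L (6.50-fold, log2 -2.70 ± 0.51, adjusted p = 0.019), Depdc1a and Shcbp1, genes of dividing cells (3.94-fold, log2 -1.98 ± 0.36, adjusted p = 0.0188, and 3.67-fold, log2 -1.88 ± 0.29, adjusted p = 0.0104), and Vcan, the proteoglycan versican (3.33-fold, log2 -1.74 ± 0.32, adjusted p = 0.0188). Proliferation and collagen genes were lower (0 higher and 22 lower, 0 and 26 adjusted over the list alone, median log2 -0.80, adjusted p = 5.53e-27, 0.14 with an estimated correlation, and 0 higher and 8 lower, 1 and 12 adjusted over the list alone, median log2 -0.51, adjusted p = 2.19e-12, 0.0912 with an estimated correlation), and ciliated airway epithelium and club and mucous airway epithelium genes higher (14 higher and 0 lower, 18 and 0 adjusted over the list alone, median log2 1.04, adjusted p = 1.97e-13, 0.255 with an estimated correlation, and 6 higher and 0 lower, 7 and 0 adjusted over the list alone, median log2 1.04, adjusted p = 6.54e-08, 0.27 with an estimated correlation), in the group with the highest Scgb1a1 share. Calls numbered 1609 (10.1%), 940 higher and 669 lower, with non-overlapping values for 5469 genes (34.4%, chance 10%), and 32 lists passed, 9 higher and 23 lower. With an estimated correlation camera passed 0 lists (9 at an unadjusted p under 0.05), and fry passed 17. The alveolar macrophage list had a median below 0 and a mean above it, and the glycolysis and hypoxia list a median and mean above 0, both with a lower camera rank. Of the 10 genes named here, only Shcbp1 kept its call whichever library was left out, and the other 9 lost it without control 4w replicate 2 and without control 4w replicate 3. Without control 1w replicate 1 the 5 muscle genes were at log2 5.08 to 7.02. Nppa and Hfe2 were at 4.00 and 3.24 without control 4w replicate 2, Eef1a2 was at 3.31 without control 1w replicate 2, and Krt14 was at -2.23 without control 1w replicate 3.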

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

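The tests of PQ 4w replicate 3, of the lymphocyte lists and of scaling were chosen only after the result was seen, while the heart ventricle test and the regrouping of labels were set before.

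What drew a closer look was a difference between the time groups in the effect of PQ, tested by the interaction term in edgeR (n = 3 per group). It passed for 5092 genes and 29 gene lists. The effect (log2, 4w minus 1w) differed by 5.98 for Jchain, 4.85 for Cd207, 4.22 for Gbp10, 3.85 for Ms4a4c and 3.79 for Dnase1l3, all higher at 4w. It differed by -6.60 for Marco, -6.58 for Tnfsf18, -5.74 for Hmga2, -5.33 for Grem1 and -5.03 for Vsig4, all lower at 4w. Among 100 splits drawn, 2 called as many genes, the real one included. The splits regroup PQ and control labels at both times, so the count argues against labels without any PQ effect. It cannot decide whether the effect differs between the times, because an effect at 1 time alone also raises it. The other was the split that exchanges all PQ 4w and control 4w labels (6335 genes). It keeps the 4 groups and tests the sum of the PQ effects at both times. The highest count without it was 4464.

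For the other comparisons 3 against 3 libraries give 10 splits, too few for a share under 0.05. The real split called 7772 genes at 1w (highest other 0), 1932 at 4w (highest other 1), 8684 between PQ 4w and PQ 1w (highest other 1) and 1609 between the controls (highest other 1). In each comparison 1 of the 10 splits, the real one, gave as many genes.

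PQ 4w replicate 3 stood apart from the other PQ 4w libraries, with higher B cell (log2 difference 1.183), interferon-induced (1.148) and T cell lists (0.7) and lower club and mucous (-2.755), ciliated (-1.13) and cardiac lists (-2.474). A mislabelled control was argued against: the macrophage list of that library was at 0.839, where the highest control was at 0.098 and the SD of PQ 4w was 0.127. Its correlation of log2 CPM goes the other way, with 0.9789 to 0.9796 against the control 1w libraries and 0.9745 and 0.974 against the other PQ 4w libraries, but a control label does not account for the macrophage level. Less airway tissue as the cause of the B cell and interferon-induced levels was argued against as well, because the 8 structural lists differed by -0.583 (smooth muscle) to 0.409 (alveolar type 1 epithelium), with an SD of 0.322, and the smaller of the 2 was 1.148. Variation between animals, which may include infection or immune state, stays open and was not tested, as does a piece of lung with more lymphoid tissue.

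NK cell, B cell and T cell lists were lower in PQ 1w than in control 1w. Dilution by other cells as the whole cause was argued against, with levels set against the mean of control 1w. The highest PQ 1w library of the NK and B cell lists was at log2 -1.451 (SD of the 3 libraries up to 0.187) and that of the T cell list at -0.932 (SD 0.096), where the lowest PQ 1w library of the 8 structural lists was at -0.785, a small margin for the T cell list. Scaling was argued against, since other scalings moved the median log2 effect by at most 0.012. A lower number of lymphocytes after PQ, an effect of the treatment that the design names, may account for these values, and cell numbers were not measured.

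The cardiac muscle list was higher in control 4w than in control 1w. Carried-over heart ventricle was argued against, because the ventricular light chains Myl2 and Myl3 came to 3.47% of the atrial light chains Myl7 and Myl4 in the highest control 4w library. Scaling was argued against with a shift of 0.0259. Atrial or pulmonary vein muscle in the tissue taken may be a source, with Nppa at 52.2 CPM in control 4w. For the difference between the controls, the amount taken cannot be separated from age, since both go with the time label. The list also varied within a time label, which that label does not account for. It was at log2 -0.145, -2.938 and -1.988 in control 1w and 0.726, 1.545 and -1.338 in PQ 4w. In each group the library lowest in this list was also lowest in the club and mucous list.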

How the results depend on the processing

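No alternative was added after the results were seen. DESeq2 adjusted p-values were missing for 3 genes in each comparison with PQ and 621 in the controls. Of 1622 alternative values for 101 named gene results, 1526 kept side of the threshold and any called direction. Calls lost were 89, gained 7 and reversed 0. Of 1671 list values 1405 kept both, 219 lost the call, 46 gained one and 1 reversed: the B cell list at 4w was at median log2 -0.363 without PQ 4w replicate 3 (passing lower), 0.175 with all libraries (not passing) and 0.44 without PQ 4w replicate 2 (passing higher), the lowest and highest of the values that passed with a library left out, and the cause was not tested. A minimum of 2-fold, a smaller set by construction, left 1961 genes at 1w, 388 at 4w, 1557 for the interaction, 2479 between PQ 4w and PQ 1w, 433 between controls and 176 shared. Only the 6 libraries compared gave 746 genes at 4w against 1932 and 451 shared against 1016, but 7896 against 7772 at 1w, 7902 against 8684 between PQ 4w and PQ 1w and 2247 against 1609 between controls, and the cause was not tested. In the fit of all 12 libraries each gene has 1 estimate of its spread, shared by the 4 groups. Its calls at 4w therefore rest in part on the spread within the other groups. With an estimated correlation camera passed 7, 3, 7, 6 and 0 lists against 31, 24, 29, 29 and 32 in the order above. The camera runs differed only in the correlation set between members, so the list calls that were lost depend on that setting. Fry passed 12 lists at 4w and 17 between controls, and the cause was not tested. Limma with no filter called 441 genes between controls against 1609, and the cause was not tested. DESeq2 called 7643, 2213, 5138, 8436 and 2356 genes.

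With each library left out in turn, fewer samples by construction, counts were 6704 to 7197 at 1w, 4107 to 5250 for the interaction and 7463 to 8604 between PQ 4w and PQ 1w, all within 1.5 times. At 4w they were 641 to 2104, with 641, 1096 and 1183 without control 4w replicates 1, 2 and 3 and 994 without PQ 4w replicate 1. Without PQ 4w replicate 3, 2104 were called at 4w, of which 1500 were among the 1932. Shared calls were 397 to 1110, with 397 without control 4w replicate 1, 652 without replicate 3 and 605 without PQ 4w replicate 1. Between controls counts were 123 to 1420, with 337 and 139 without control 1w replicates 1 and 3 and 678, 123 and 159 without control 4w replicates 1, 2 and 3.

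The share higher among calls at 4w was 47.4%, against 55% (size factors), 68.5% (total counts) and 63.5 to 65.2% (limma). Between controls it was 58.4%, against 49.9% (size factors), 48.1% (DESeq2) and 23 to 59.6% with a library left out. Scaling moved the median log2 of all genes by at most 0.0718, above the medians of the basement membrane, p53, TGF-beta, immediate early, alveolar macrophage, monocyte, glycolysis and lipid lists at 4w, whose sign is therefore not fixed. No list that passed reversed with size factors.

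Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated with a median of -0.06, and 5 of 18 pairs were above 0.1. With a replicate block the counts were 7636, 1646, 4826, 8453 and 1447 genes, and 890 shared. Depth, at 17220978 to 18559809 counts per library, limits folds of genes with few counts, such as Tnfsf18 with 2 counts in control 1w.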

Other observations

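H2-Ab1, Cd74 and Ciita were lower than in control at 1w and higher at 4w, and the genes of these paragraphs were chosen after their values were seen (edgeR adjusted p, n = 3 per group). H2-Ab1, a chain of the class II molecule, was at 0.579 times the control at 1w (adjusted p = 0.000194) and 2.08 times at 4w (adjusted p = 0.000633), a difference of log2 1.84 ± 0.17, adjusted p = 3.25e-05. Cd74, the invariant chain, was at 0.594 and 1.98 times (adjusted p = 0.000595 and 0.0014). Ciita, the transactivator of class II genes, was at 0.638 and 2.42 times (adjusted p = 0.0384 and 0.00595). Each of these had all 3 PQ libraries beyond all 3 controls at both times. Arg1, an arginase of activated macrophages, rose 38.2-fold at 1w and 4.21-fold at 4w (adjusted p = 9.28e-07 and 0.00947). Spp1, the matrix protein osteopontin, rose 18.8-fold at 1w and did not pass at 4w (adjusted p = 2.85e-07 and 0.163). Among alveolar macrophage genes, Mrc1, a mannose receptor, rose at both times (3.56- and 1.87-fold, adjusted p = 1.32e-08 and 0.000156), while Chil3, whose paralog Chil4 has a close sequence, passed at 1w and not at 4w (4.40-fold, adjusted p = 2e-06).

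Arntl, Dbp and Per3 differed between PQ and control and between the controls. Arntl, a core activator of the clock, was at 0.412 times the control at 1w, 0.479 times at 4w and 0.558 times in control 4w against control 1w (adjusted p = 0.0001, 0.00451 and 0.0224). Dbp, a clock output factor, was at 2.73, 1.97 and 5.70 times in the same comparisons (adjusted p = 0.000553, 0.0161 and 0.00407). Per3, a clock repressor, was at 2.02, 1.66 and 2.11 times (adjusted p = 0.00022, 0.0103 and 0.00946). Nr1d1, which represses Arntl, was at 0.363 times at 1w (adjusted p = 3.1e-05) and did not pass at 4w (adjusted p = 0.614). The hour of harvest is not given in the sources used here. Gsta2, a glutathione transferase, was at 0.125 and 0.363 times the control at 1w and 4w (adjusted p = 0.000671 and 0.0359), and Prdx6, a peroxiredoxin of surfactant cells, at 0.592 and 0.740 times (adjusted p = 2.64e-05 and 0.00986).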
